A study of Mus musculus with 8 samples.

How the data were processed

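Hippocampal total RNA from 8 samples of C57BL6/J female mice was measured on one-colour Agilent arrays labelled with Cy3. Per the labels, the mice were 8 weeks old, were housed for 4 weeks in an enriched environment (cages with added objects and space), and received either a control antibody or an antibody against CD4, the surface protein of helper T lymphocytes. Each group held 4 samples, mapped from the sample titles, which also give the replicate numbers. No label says that the samples came from separate animals, so p-values measure the spread between these samples, which may be technical. The cell depletion itself was not measured in these data.

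The deposited scanner files hold spot intensity values made with Feature Extraction 10.7.3.1 on array design 028005, per the file headers. The processed signal is an intensity that the software had background-subtracted and detrended within each array, per the file headers, with no normalization between arrays. A further deposited table by the authors holds log2 values for the same 55681 probes. Each of its columns followed the median spot signal of its own array with a rank correlation of 0.999977 or more, and its sorted columns differed by at most 0.121. The columns had medians of 7.83, so the scale is log2, the values had not been background-subtracted, and the columns had been brought close to one distribution. The submitters' processing notes name limma, and other steps are not given in the sources used here.

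All 8 arrays lay on 1 slide with 1 scan. The 4 anti-CD4 arrays filled the first row of the slide and the 4 control arrays the second, so slide row and group cannot be told apart. The slide column equals the replicate number. Between 51.1% and 54.3% of probes were well above background per array, and no probe was saturated. The number of arrays limits the precision.

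Control spots were left out and spots of one probe were averaged. Outlier-flagged spots were left out of that average, but a probe whose spots were all flagged kept their average. Flagged spots numbered 109 ± 11 per control array and 159 ± 22 per anti-CD4 array (SD, n = 4, exact permutation p = 0.0286). The main values were log2 of the processed signal minus each array's 75th percentile. A probe was tested where it was well above background on at least 4 of the 8 arrays, which kept 29403 probes. Probes were named through a table of gene symbols (GRCm38.p6) by accession for 27509 probes, by symbol for 3549 and by synonym for 367. The name in the files was kept for 1578 probes, and 22678 had no gene name. A gene with several tested probes was represented by its brightest probe, which left 23605 rows, 15887 with a gene symbol. Probe coordinates are those of the files, on mm9. The symbol table was used for names only.

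Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences are anti-CD4 minus control on the log2 scale. A gene not well above background on any array of a group was given as a bound, its brighter group's mean set against the dimmer group's mean of, per array, the higher of the gene's own signal and the lowest signal of a probe well above background. Gene lists of cell types, brain regions, dissection neighbours, blood, synapses, activity, neurogenesis and immunity were tested with camera at a preset correlation of 0.01 where at least 5 members were measured, which gave 40 lists. Means of a list per array, Cd4 and array measures were compared with exact two-sided permutation tests over 70 assignments, whose smallest p is 0.0286. In 10 sets of simulated arrays with the spread of the real genes, comparing 4 arrays with 4 over 23605 rows, the test recovered 81.6% of genes changed by 1 on the log2 scale and 42.0% of those changed by 0.5, and called 0.0252% of unchanged genes. A simulated list shift of 0.25 was called in 10 of 10 sets, with 0 of 390 other lists called; these simulated genes varied independently.

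Before the data were examined, the rule for named genes was fixed. It took up to 12 genes per direction past the threshold by size. Where fewer passed, it filled up to 8 per direction with the smallest unadjusted p among genes whose groups did not overlap, leaving out clone and predicted names. It added up to 4 members with the smallest p for each list described, and always Cd4, Cd3e, Cd8a, Bdnf, Dcx, Arc, Gfap and Ttr. Some genes that the rule takes are not reported here. Genes outside the rule are said to have been chosen after their values were seen. Alternatives covered the normalization, the background correction, the filter on dim probes, the probe of a gene, the replicate number as a block, the empirical Bayes options, array weights, the authors' table, each array left out, the set test and a threshold of 0.1. Covariates for choroid plexus and dentate signal were added after seeing the data.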

Results

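Gene expression was measured in the hippocampus of mice housed in an enriched environment that had received an anti-CD4 antibody (n = 4) or a control antibody (n = 4). The comparison addresses whether removal of CD4-positive T lymphocytes alters hippocampal transcription. All values are log2 signals relative to the array's 75th percentile, and differences are anti-CD4 minus control. Arrays correlated at 0.988 to 0.996 within groups and at 0.986 to 0.994 between groups.

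No gene passed the adjusted threshold in limma, in either direction. At an unadjusted p under 0.05 there were 3067 of 23605 genes and unnamed probes, 1455 higher and 1612 lower in the anti-CD4 group. On average 1180 would arise if none had changed. Genes do not vary independently, and other splits of the 8 arrays into 4 and 4 gave 379 to 2792. Among the 3067, genes with characterised names were 1015 higher and 799 lower. Unnamed probes and genes with clone or predicted names were 440 higher and 813 lower. The smallest adjusted p was 0.119. The groups did not overlap for 1933 genes, 8.19% of those tested, against 2.86% by chance. Centring each array on its median turned the balance to 2067 higher and 958 lower. Repeat-probe variation was larger on the anti-CD4 arrays, with a median CV of 4.88% ± 0.111 (SD, n = 4) against 3.77% ± 0.165 (exact permutation p = 0.0286, the smallest possible), and slide row coincides with group.

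For Cd4, which encodes the antigen of the antibody, the tested probe differed by 0.02, less than the spread between replicates. This probe, at chromosome 6, 124814711 to 124814770 (mm9), read 2.03 ± 0.15 in controls and 2.05 ± 0.12 in the anti-CD4 group (SD, n = 4; exact permutation p = 0.857). The other Cd4 probe read -6.27 in controls and -6.33 in the anti-CD4 group and was not well above background on any array. The value therefore rests on a single probe, and the 2 probes disagree on the level of Cd4. Whether the tested probe reads Cd4 of T lymphocytes was not tested. Cd3e, a component of the T-cell receptor complex, differed by 0.01 (adjusted p = 0.970, limma). Both Cd8a probes failed the filter on dim probes. Only 6 of 24 genes of the T lymphocyte list were measured, and the list did not pass the test (adjusted p = 0.723, camera).

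Among genes with separated groups, the smallest p-values on the higher side belonged to genes with differences of 0.42 to 0.65, none past the adjusted threshold. Lcn2, which encodes the iron-siderophore-binding protein lipocalin 2, read -2.89 ± 0.08 in controls and -2.24 ± 0.09 in the anti-CD4 group, a 1.57-fold difference (SD, n = 4; adjusted p = 0.119, limma). Dipk1b was 0.63 above controls, Zic5, a zinc finger transcription factor, 0.50, and B3gat3, an enzyme of glycosaminoglycan linker synthesis, 0.46. Gpr183, a receptor for oxysterols that guides immune cells, and Retreg2 each differed by 0.43, and Ppm1a, a protein phosphatase, by 0.42. On the lower side, Uba6, a ubiquitin-activating enzyme, read -1.11 ± 0.07 in controls and -1.67 ± 0.05 in the anti-CD4 group, a difference of -0.56 (adjusted p = 0.119). Plb1 differed by -0.68, Mamdc4 by -0.62, the noncoding Srrm4os by -0.57 and Ercc6, a DNA repair factor, by -0.48. Zfp317 differed by -0.38, Sptlc1, a subunit of the first enzyme of sphingolipid synthesis, by -0.36, and Shank3, a scaffold of excitatory synapses, by -0.32 (adjusted p = 0.177). The differences of Lcn2, Gpr183 and Plb1 were 0.32, 0.24 and -0.27 with normexp background correction and 0.19, 0.15 and -0.18 with the authors' table, where Zic5, Mamdc4 and Uba6 differed by 0.32, -0.39 and -0.37. The values of Uba6 and Shank3 come from the brighter of 2 tested probes, and the means of both probes differed by -0.28 and -0.21.

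Of the 40 gene lists, 10 passed the threshold with camera's preset correlation, 7 higher and 3 lower in the anti-CD4 group. None passed with an estimated correlation. The antigen presentation list was higher (adjusted p = 1.43e-05; adjusted p = 0.901 with an estimated correlation), with 16 of 17 measured members above controls. No member passed over all genes, and 8 did adjusted over the list alone, all higher. H2-T23, a nonclassical class I molecule, was 0.43 ± 0.075 (SE) above controls, the class I heavy chain H2-D1 0.30 ± 0.078, the peptide transporter Tap1 0.48 ± 0.131 and the class II chain H2-Ab1 0.75 ± 0.211. Tap1 was well above background on 1 control array and on 4 anti-CD4 arrays, and its difference was 0.18 with normexp and 0.08 with the authors' table. B2m, chosen after its value was seen, differed by 0.08. The mean of the list differed by 0.26 (exact permutation p = 0.0286, 0.229 after adjustment over 40 lists).

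The red blood cell list was higher as well (adjusted p = 8.08e-05; adjusted p = 0.752 with an estimated correlation). Of its 8 measured members 6 were higher, and the same number passed adjusted over the list alone. The hemoglobin genes Hbb-bt, Hba-a1 and Hbb-bs were 0.41, 0.49 and 0.70 above controls, and Alas2, the erythroid enzyme of heme synthesis, 0.63. Hemoglobin genes have near-identical copies, and probes of one may read another. The interferon response list passed (adjusted p = 0.0231; 0.901 with an estimated correlation), with 15 of 19 members higher and 0 adjusted over the list alone. Irgm1, a GTPase of cell-autonomous immunity, differed by 0.25, or by 0.07 as the mean of its probes, which went opposite ways, and Rtp4 and Oasl2 by 0.29 and 0.39. The interferon median of 0.17 was 0.02 without control replicate 3, and the list then did not pass (adjusted p = 0.494), nor without anti-CD4 replicate 4 (adjusted p = 0.0664) or with Ttr signal or the dentate list's mean as a covariate, chosen after seeing the data (adjusted p = 0.145 and 0.110). Its mean was -0.29 in control replicate 3 and 0.06 to 0.13 in the other controls, against 0.05 to 0.26 in the anti-CD4 arrays (exact permutation p = 0.143).

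The proliferation list was lower (adjusted p = 0.00783; adjusted p = 0.901 with an estimated correlation). Of 15 measured members 11 were lower, and 4 passed adjusted over the list alone. Cyclin A2 (Ccna2) differed by -0.43 ± 0.111 (SE), Ube2c, which tags mitotic proteins for degradation, by -0.69 ± 0.197, and the proliferation marker Mki67 by -0.54 ± 0.164. With the authors' table Ccna2 and Ube2c differed by -0.22 and -0.21. Markers of dentate granule neurons were also lower, in 13 of 15 members (adjusted p = 0.0298; 0.901 with an estimated correlation). Prox1, their transcription factor, differed by -0.52 and Npnt by -0.49 (-0.13 with normexp and -0.07 with the authors' table), while Calb1, a calcium-binding protein of these neurons, was 0.43 above controls. The dentate list mean was -0.53 and -0.36 in anti-CD4 replicates 2 and 4, and -0.0063 and 0.02 in replicates 1 and 3, within the control range of -0.17 to 0.23 (exact permutation p = 0.229). The list did not pass without control replicate 2 or 3 or anti-CD4 replicate 2 or 4 (adjusted p = 0.194, 0.163, 0.214 and 0.148), and its median of -0.22 was -0.12 without anti-CD4 replicate 2 and -0.33 without replicate 3. It did not pass either with quantile normalization (adjusted p = 0.0505), with probes well above background on all arrays (0.0755), with the authors' table (0.0658, median -0.14) or with the Ttr covariate (0.220), and its median was -0.14 with normexp. The immature neuron marker Dcx differed by 0.09 (adjusted p = 0.802, limma). The proliferation list did not pass with the authors' table (adjusted p = 0.0604) or with the dentate list's mean as a covariate, chosen after seeing the data (adjusted p = 0.0957).

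Myelin genes were lower in 13 of 18 members (adjusted p = 0.0284; 0.901 with an estimated correlation), among them Aspa at -0.29, Ugt8a at -0.34, Mog at -0.29 and Sox10 at -0.25. The myelin mean was 0.16 in anti-CD4 replicate 3, above each control array, and -0.25 to -0.11 in the other anti-CD4 arrays (exact permutation p = 0.486). The list did not pass without control replicate 1 or 2 or anti-CD4 replicate 1, 2 or 4 (adjusted p = 0.146, 0.0890, 0.0575, 0.239 and 0.0664), and its median of -0.15 was -0.07 without control replicate 2 and -0.09 with the dentate covariate (adjusted p = 0.534). Endothelial and pericyte genes passed in the other direction with 12 of 19 members higher (adjusted p = 0.0284; 0.901 with an estimated correlation). Flt1, a receptor of vascular growth factor, differed by 0.33, the junction protein Esam by 0.24 and the glucose transporter Slc2a1 by 0.17, whereas Cldn5 and Ly6c1, chosen after their values were seen, differed by 0.08 and -0.04. With Ttr signal as a covariate, chosen after seeing the data, the endothelial list did not pass (adjusted p = 0.158), nor did it without anti-CD4 replicate 3 (adjusted p = 0.0785). Its median difference of 0.08 turned to -0.03 without control replicate 3 and to -0.0014 without anti-CD4 replicate 4 (adjusted p = 0.494 and 0.108), and was 0.14 without control replicate 2 and 0.12 without anti-CD4 replicate 1. Ribosomal protein genes passed with 24 of 30 members higher (adjusted p = 0.0284; 0.901 with an estimated correlation), with Rpl4 at 0.18, Rpl35 at 0.18 and Rpl30 at -0.15. That list did not pass without control replicate 1 or 4 or anti-CD4 replicate 1 or 4 (adjusted p = 0.201, 0.0924, 0.206 and 0.229), and its median of 0.07 was 0.04 without control replicate 1 and 0.05 without anti-CD4 replicate 1. With quantile normalization and with the authors' table the ribosomal median was 0.02 (adjusted p = 0.484 and 0.684), and the list did not pass with normexp, the mean of a gene's probes, all probes or the replicate block (adjusted p = 0.154, 0.111, 0.0660 and 0.0596).

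Neuropeptide and hormone receptor genes were higher in 20 of 27 members, and the striatum list in 9 of 11 (adjusted p = 0.0284 for each; 0.901 for each with an estimated correlation). The neuropeptide precursor gene Trh read 2.68, 2.37, -2.49 and 2.34 in anti-CD4 replicates 1 to 4 and between -4.36 and -2.94 in the controls. Esr1, the estrogen receptor gene, was well above background on no control array. Its group mean was at least 2.24-fold higher in the anti-CD4 group (adjusted p = 0.220, limma). It read -3.91 in anti-CD4 replicate 3, -2.96 to -2.56 in the other anti-CD4 arrays and -4.36 to -4.05 in controls. Tac1 and Tac2, which encode tachykinin peptides, differed by 0.58 and 0.47, and Penk, the enkephalin precursor, by 0.56. In anti-CD4 replicate 3, Tac1, Tac2 and Penk lay within the control range. Without anti-CD4 replicate 3, 11 genes and unnamed probes passed the threshold, Trh and Esr1 among them (adjusted p = 0.00562 and 0.0368, limma). The neuropeptide list did not pass without control replicate 2 or 4 or anti-CD4 replicate 1, 2 or 4 (adjusted p = 0.0771, 0.0640, 0.0771, 0.0605 and 0.0892). Its median of 0.17 was 0.08 with normexp, 0.10 with the authors' table and 0.08 with the dentate covariate, and the list did not pass with these (adjusted p = 0.118, 0.196 and 0.129), with quantile normalization (0.0644) or with probes well above background on all arrays (0.121). The striatum list did not pass without control replicate 2 or anti-CD4 replicate 2 or 4 (adjusted p = 0.0820, 0.0938 and 0.0510), and its median of 0.27 was 0.11 without control replicate 2 and 0.18 without anti-CD4 replicate 2. Nor did it pass with normexp, with probes well above background on all arrays or with the authors' table (adjusted p = 0.0508, 0.0522 and 0.0604), or with the dentate covariate (median 0.04, adjusted p = 0.364). The thalamus and habenula list had 12 of 13 members higher and did not pass (adjusted p = 0.0510), but passed in 9 of the alternative settings.

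Choroid plexus signal varied between arrays of both groups. Ttr, the transthyretin gene that dominates choroid plexus, gave processed signals of 264038, 5576, 538 and 224770 in control replicates 1 to 4 and 1675, 147188, 274131 and 156926 in the anti-CD4 replicates. The choroid plexus and ependyma list did not pass (adjusted p = 0.335, camera), with a median difference of 0.83. It passed without control replicate 1 (median 1.55, adjusted p = 0.0131) and without anti-CD4 replicate 1 (median 1.83, adjusted p = 0.010). Immediate early genes, which report recent neuronal activity, did not pass either (adjusted p = 0.545), with Arc at -0.26, Nr4a3 at -0.70 (-0.11 with the authors' table) and Jun at -0.13. Bdnf differed by -0.30 and the astrocyte gene Gfap by -0.25 (adjusted p = 0.510 and 0.390, limma). The microglia and macrophage list had 12 of 19 members higher and did not pass (adjusted p = 0.511), although Adgre1 was 0.34 above controls.

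**Figure D1:**
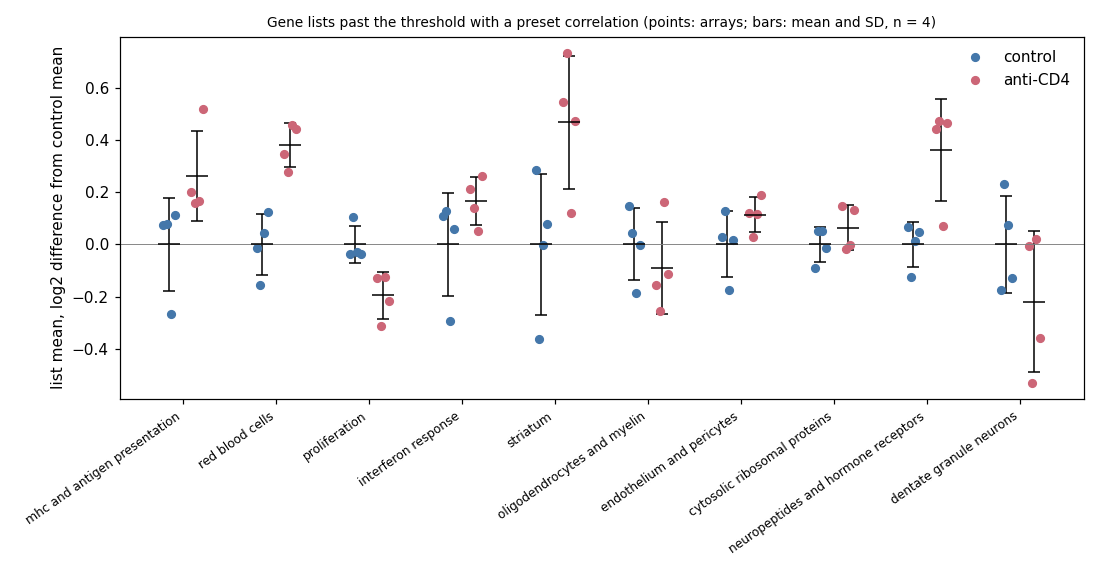
Mean of each gene list per array as the log2 difference from the control mean (vertical axis), for the 10 lists past the threshold with a preset correlation. Points are arrays, and bars give mean and SD (n = 4 per group); the red blood cell mean was 0.38 above controls and the proliferation mean -0.20.

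**Figure D2:**
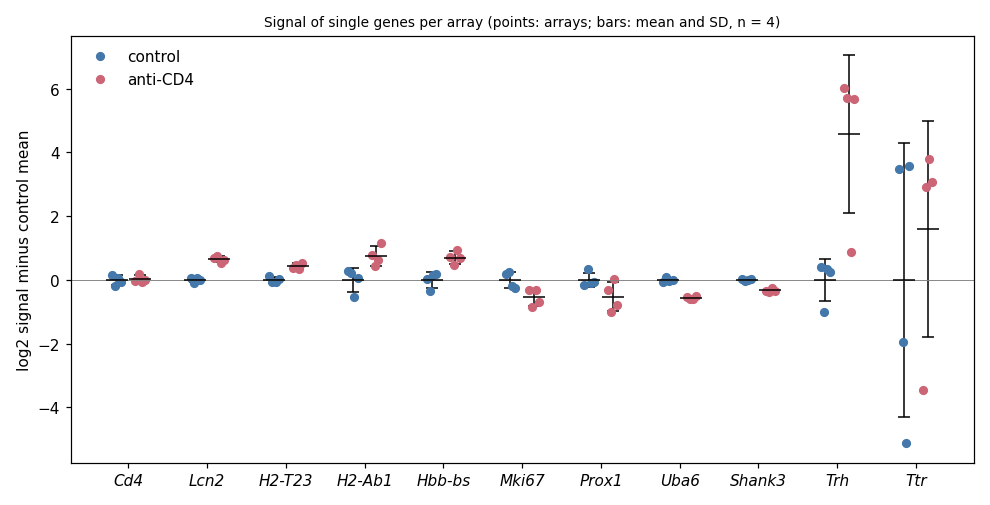
Log2 signal of single genes per array relative to the control mean (vertical axis), with points for arrays and bars for mean and SD (n = 4 per group). The tested Cd4 probe differed by 0.02, and Trh was high in 3 of 4 anti-CD4 arrays.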

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

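A single array stood apart from the others of its group by a gap test in 13 of 244 groups of values examined (5.33%), where chance gives about 1 in 20. The tests of explanations here on neighbouring tissue and on the number of gene lists were fixed before their results were seen; those on blood, vessels and the counts of genes were chosen after.

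Trh lay at -2.492 in anti-CD4 replicate 3, below 2.335 to 2.678 in the other anti-CD4 arrays, and at -4.356 in control replicate 2. The neuropeptide list mean was 0.06936 in anti-CD4 replicate 3 against 0.4404 or more in the others. Tissue of the hypothalamus or medial amygdala taken along is a candidate explanation. A list of other genes of these regions had a median difference of 0.3407, with 14 of 15 measured members higher, Ngb by 1.33 and Zcchc12 by 0.80, and a mean near 0 in anti-CD4 replicate 3 (-0.003661). Hippocampus expresses several of these genes too, so an effect of the treatment on these genes stays open and untested. The list mean did not separate the groups (exact permutation p = 0.114). Anti-CD4 replicate 3 lay within the control range of -0.245 to 0.114, and the other anti-CD4 arrays read 0.399 to 0.730. This overlap cannot tell the explanations apart.

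The antigen presentation list mean was 0.5178 in anti-CD4 replicate 4 and -0.2647 in control replicate 3, and the interferon list mean was -0.2916 in control replicate 3. Neither more vessel tissue nor residual blood can be told apart from an effect of the treatment. The endothelial and pericyte list, itself higher, had a median of 0.08015 with a standard error of 0.04918, below a bound of 0.1342. Without control replicate 2 that median was 0.1427, above the bound of 0.1207 then. These bounds were set from the antigen presentation list's own median. More vessel tissue need not raise both lists in that proportion, so the bounds cannot decide. Transcripts of blood leukocytes had a median of 0.1399 over 5 measured genes, with a standard error of 0.261. Their median was -0.025 without control replicate 2 and 0.329 without control replicate 4. Their mean was highest in anti-CD4 replicate 4 (0.962) and lowest in control replicate 3 (-0.415), against -0.0804 to 0.399 in the other arrays. The endothelial list mean was highest and lowest in the same arrays (0.190 and -0.174). The demands that a median exceed its standard error and that a bound hold without each array were added after the list medians were seen. S100a8 and S100a9, abundant in neutrophils, differed by 0.88 and 0.80, neither past the threshold. Slide row coincides with group and stays open for every pattern.

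Other values that stood apart were Gpr183 at -3.893 in control replicate 4, Lck at -0.7573 in anti-CD4 replicate 3 and Ttr at 1.218 in anti-CD4 replicate 1. List means that stood apart were -0.261 for neocortex and subiculum and 0.1046 for proliferation in control replicate 2, and -0.1193 for the postsynaptic density and -0.1334 for voltage-gated channels in control replicate 1.

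Of the 35 ways to split the 8 arrays, 1, the real one, reached the real 3067 genes at an unadjusted p under 0.05. The highest other count was 2792, so chance assignment of arrays is argued against for this count but not excluded. The test was chosen after the count was seen, and 1 of 35 is the smallest share it can give. Slide row cannot be excluded either. For genes past the adjusted threshold the real count was 0, which all 35 splits reach, so this count tests nothing about chance. The highest other count was 25, in the split that exchanges control replicate 4 and anti-CD4 replicate 3, and the remaining splits gave 0. For gene lists 8 of 35 splits gave 10 or more, up to 15, so chance cannot be excluded.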

How the results depend on the processing

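The Ttr and dentate covariates were chosen after seeing the data; all other alternatives were fixed before. No gene passed the threshold under 10 of the planned settings or at a threshold of 0.1. With trend and robust eBayes 2 unnamed probes passed, and the same 2 with the authors' table, both lower in the anti-CD4 group. Leaving out 1 array gave 0 to 11 genes and unnamed probes in total, 0 to 9 higher and 0 to 2 lower, with 11 only without anti-CD4 replicate 3. The count at an unadjusted p under 0.05 ran from 2188 to 3723 when 1 array was left out and from 2210 to 3875 under the other settings. List counts ran from 3 (without anti-CD4 replicate 4) to 11 when 1 array was left out, with 6 without control replicate 2. They were 13 with array weights, 12 with no filter on dim probes, 11 with trend and robust eBayes, 5 with the authors' table, 5 with the dentate covariate, 0 with camera's estimated correlation and 0 with fry. The antigen presentation, red blood cell and proliferation lists passed without each array in turn; the other 7 were lost without at least 1. Of 14 settings that kept all arrays and the preset correlation, the antigen presentation and red blood cell lists passed in 14, proliferation in 12, myelin and endothelium in 13 each, interferon in 12, striatum in 10, dentate and neuropeptides in 9 each and ribosomal proteins in 8. For the dentate list, 1 of the 14 settings used its own mean as a covariate, which removes its difference by construction. The endothelial median of 0.08 turned to -0.03 without control replicate 3 and to -0.0014 without anti-CD4 replicate 4, where the list did not pass. Lists that passed only under an alternative were thalamus and habenula in 9 settings, leptomeninges in 3, choroid plexus in 2, and complement and heat shock in 1 each. Of 114 named genes with an unadjusted p under 0.05, the difference shrank by over 1.5 times in 33 with the authors' table, 19 with normexp, 17 with the dentate covariate and 14 with the mean of a gene's probes, where 1 more changed sign. The cause was not tested. The difference of the tested Cd4 probe ran from -0.04 to 0.07 without 1 array. The replicate number as a block gave 0 genes, 2210 at an unadjusted p under 0.05 and 10 lists. Deviations of same-numbered arrays correlated at -0.454, -0.288, -0.307 and 0.305 for replicates 1 to 4. Control replicate 4 reached at most 0.107 with the other anti-CD4 arrays. Pairing by number was thus not seen throughout, but these values cannot exclude it. With Ttr as a covariate 0 genes and 7 lists passed. Slide as a block was not run, since 1 slide held all arrays. Signal over background limits Cd8a and most T lymphocyte genes, which were too dim to compare.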

Other observations

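The list of other nuclear noncoding RNAs was written before its values were seen; the tests on strand and on matched probes, and the choice of the interval itself, came after.

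On chromosome 7 between the probe of Ube3a and the nearest probe of Snrpn (66561330 to 67127426, mm9), noncoding RNA read from the reverse strand was lower in the anti-CD4 group. Of 25 reverse-strand probes 24 were lower, with a median difference of -0.5372, and the groups did not overlap for 16 of them, against 8.19% of all tested genes and 2.86% by chance; these probes are not independent of each other. Their mean differed by -0.46 (exact permutation p = 0.0286, the smallest possible). Examples, chosen after their values were seen, were Ipw at -0.49, Snord116 at -0.51 and Snhg14 at -0.28, the long host transcript of this imprinted region. Beside it, the Ube3a probe differed by -0.10 and the Snrpn probes, from the nearest outward, by -0.0039, -0.06 and -0.10, the last with separated groups. No probe passed the threshold in the main comparison, but the 2 unnamed probes past it with trend and robust eBayes and with the authors' table, at 66829544 and 66868793, lie here.

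A shift of every probe of the interval is argued against by its 25 forward-strand probes, with a median of -0.07226. Without 1 array that median ran from -0.0903 (without control replicate 2) to -0.0244 (without anti-CD4 replicate 4). Many forward-strand probes lie close to the Ube3a probe, at 66563347 to 66565105, and may not be independent of each other. None lies between 66576775 and 66891025, where the reverse-strand probes at 66829544 and 66868793 lie. A shift on both strands was thus not tested there. A general shift of dim noncoding probes is argued against by 10000 random sets matched on signal, whose medians reached -0.2 at the lowest. These sets hold probes from outside the interval, while the interval's probes are not independent and were chosen after their values were seen. The sets therefore do not measure how often probes of one region would differ this much by chance. Lower recovery of nuclear RNA was taken to need a median at or below -0.27 in other nuclear noncoding RNAs. This bound was set from the interval's own median. Theirs was -0.1361 (standard error over genes 0.0651), -0.0503 without control replicate 1 and -0.186 without control replicate 4. These medians lay above the bound, but other nuclear RNA need not fall by that share, and the standard error is not over arrays. The test cannot decide how far lower recovery contributes, since 9 of 11 were lower and Malat1 differed by -0.49. The reverse-strand probes differed by 0.12 to -1.01 and most have no gene name, so whether they read 1 transcript was not tested. A lower level of reverse-strand RNA from this interval after anti-CD4 treatment may be considered as a hypothesis. It was found and tested on the same arrays, and slide row coincides with group throughout.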
